A study of Homo sapiens with 57 samples.

How the data were processed

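RNA sequencing of urinary cells from kidney allograft recipients was analysed from 57 processed files, 1 per library. Per the labels' protocols, total RNA was isolated with an RNeasy kit and libraries were made with a TruSeq sample preparation kit. The FPKM values were made by the authors with STAR and Cufflinks on the build hg38, per the submitters' processing notes. Tool versions, the annotation release, the read length and any filter are not given in the sources used here. Per the file headers, each file held 1 deposited FPKM column for Ensembl gene identifiers. FPKM divides by the length of a gene and by the total mapped fragments, so a few very abundant RNAs lower the values of all other genes in a library, and read depth cannot be recovered from them. Because depth is unknown, no counting interval is given.

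The files held 60466 identifiers, of which 56317 (93.1%) were named in the gene table used here. Rows on the Y chromosome and XIST and TSIX (610 rows) were left out of every step. Rows with 1 symbol were summed (73 symbols), which left 58706 genes. In 2 NR libraries some rows were missing, 1 in one and 18 in the other, and such genes were fitted on the remaining libraries and left out of list tests. This removed the list test of mitochondrially encoded genes. MT-RNR2 was listed at 0 in 6 libraries, which can be a failed estimate, while 12 housekeeping genes were above 0 in all libraries. The highest correlation of log2(FPKM + 1) between 2 libraries was 0.956 and the median 0.866, so no pair of libraries held the same values. Coordinates are those of the GENCODE 29 annotation of GRCh38, matched by identifier.

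Libraries were grouped by the diagnosis in the labels. Replicate numbers follow the order of deposit and only name a library. Library names fall into 2 series, starting with U or GEM (3 and 5 AMR, 4 and 23 NR, 4 and 18 TCMR libraries), and the column headers divide the GEM series again by the letters RG, which 0 AMR, 11 NR and 13 TCMR libraries carry. What these series stand for is not given in the sources used here.

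The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with trend and robust moderation, all 57 libraries in 1 fit and the U or GEM series as a covariate. Genes with an FPKM of at least 1 in at least 8 libraries were tested, 11576 in all, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The verbs rose and fell are used for called genes. The groups compared were TCMR and NR, AMR and NR, and TCMR and AMR. The file unit was the one assumed when the design was fixed.

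There were 35 gene lists, fixed before the data were examined, as were the design, the rule for named genes and the first set of alternatives. Lists with at least 5 tested members (30 lists) were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way and compares it with no other genes. Counts of members called over all genes and adjusted over the list alone stand beside them. The genes named were, per comparison, the 10 called genes with the largest positive and the 10 with the largest negative difference at a mean log2 level of at least 2 in the higher group (at least 1 where fewer than 10 remained), without small RNA genes, antigen receptor segments and unnamed loci. To these were added up to 4 members of a described list with the smallest p, the most abundant member of a list not called, and tested members of the urine panel. A few genes that this rule names are not reported here.

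Median-of-ratios scaling divided each library by the median of its ratios to the geometric mean over genes above 0 in all libraries. The factors had a geometric mean of 1.197 in TCMR, 1.268 in AMR and 0.805 in NR. Other alternatives were quantile normalization, a pseudocount of 0.1, no filter, a stricter filter, no covariate, a term for names with a letter b, each series alone, fits of the compared groups alone, array weights, an exact rank-sum test and leaving out each library. Chosen after seeing the data were the header series as covariate, scaling to the FPKM outside mitochondrial, 7SL and 7SK rows, libraries with at least 4000 detected genes, the number of detected genes or a score of 13 general leukocyte genes as a further covariate, and combinations with median-of-ratios scaling.

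The fit was tested on simulated data with the means and SDs of 11566 real genes in NR, each gene drawn independently. For TCMR against NR it recovered 74% of 100 genes changed by 1 on the log2 scale and 98% of 100 changed by 2, with 7 calls among the unchanged genes. For AMR against NR the shares were 42% and 86%, with 6 such calls. In the real data genes move together (estimated correlation within lists of 0.149 to 0.93). These calls therefore do not give the error rate of the fit there. For shared controls, all libraries were redrawn 40 times with no group effect from the fitted residuals. The numbers of called genes were compared with those of 100 splits of the same libraries, the real one included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.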

Results

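Urinary cells were profiled by RNA sequencing in recipients of a kidney allograft, a transplanted kidney, at the time of a biopsy. The diagnosis put each library in a group. There were 22 libraries with T cell mediated rejection (TCMR), 8 with antibody mediated rejection (AMR) and 27 with no rejection (NR), a group that takes in normal biopsies and nonspecific changes. TCMR is rejection driven by recipient T cells that enter the graft, and AMR is rejection driven by antibodies against donor antigens. Urine pellets hold cells shed from the tubules, the bladder lining and the outer urinary tract, together with leukocytes. The labels do not say whether any recipient gave more than 1 pellet, so p-values measure the spread between libraries.

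The values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 58706 genes after rows of the same symbol were summed. Sequencing depth is unknown, because FPKM carry no read totals. The number of genes at an FPKM of 1 or more served as a guide to library quality and ranged from 2339 to 11964, with a median of 7713. It averaged 8125 ± 2476 (SD, n = 22) in TCMR, 8408 ± 2093 (SD, n = 8) in AMR and 6474 ± 1914 (SD, n = 27) in NR. A few rows held most of the signal. The 5 highest rows of a library took between 19.9% and 87.6% of its FPKM sum, with a median of 67.4%. Mitochondrial rows took 44.2% ± 24.3 (SD, n = 22) of the sum in TCMR, 50.6% ± 18.8 (SD, n = 8) in AMR and 54.2% ± 21.3 (SD, n = 27) in NR. The small nuclear and cytoplasmic RNAs 7SK and 7SL took a median of 15.3% in TCMR, 13.2% in AMR and 11.1% in NR. Nuclear protein-coding rows took a median of 24.1%, 16.9% and 15.1%.

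**Figure D1:**
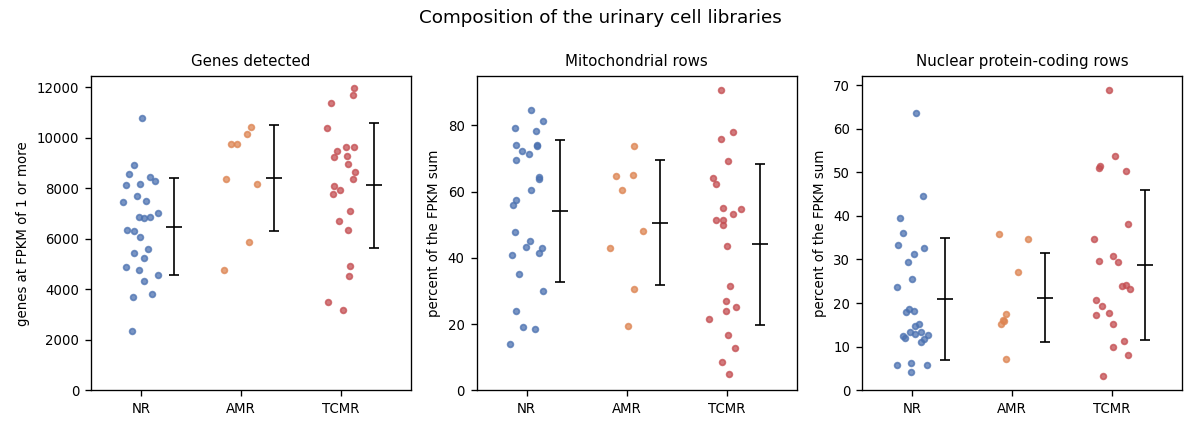
Genes detected (number of genes at an FPKM of 1 or more) and the share of the FPKM sum (percent) in mitochondrial and in nuclear protein-coding rows. Points are libraries of the NR, AMR and TCMR groups with the group mean and SD as black bars, the groups overlap in every panel, and genes detected average 6474 in NR against 8125 in TCMR and 8408 in AMR.

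The first comparison asked which transcripts of urinary cells differ between TCMR and no rejection. Genes of antigen presentation and of the response to interferon gamma were higher in TCMR, and so were genes of T cells, cytotoxic lymphocytes and macrophages, while genes of the proximal tubule and of squamous epithelium lay lower. HLA-DRA, the alpha chain of the MHC class II molecule HLA-DR (chromosome 6, 32439842 to 32445046), was higher by 1.96 ± 0.47 on the log2 scale (SE, limma adjusted p = 0.00497). CD74, the invariant chain that guides class II molecules (chromosome 5, 150401637 to 150412929), was higher by 1.94 ± 0.46 (SE, limma adjusted p = 0.00497). GATM, the first enzyme of creatine synthesis, fell by 1.13 on the log2 scale (SE 0.34, limma adjusted p = 0.00959). Of 11576 genes tested with limma, 5358 passed an adjusted p of 0.05, and 5306 of them were higher in TCMR against 52 lower.

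This lopsided split moved with the scaling between libraries. The median gene was 0.35 higher on the log2 scale in TCMR than in NR with the FPKM as deposited, and 0.02 higher after median-of-ratios scaling, which lines libraries up on their typical gene. With that scaling 1059 genes passed, 616 higher and 443 lower, and 663 genes passed in the same direction with both. Leaving out 1 library at a time after that scaling gave between 231 genes (without TCMR replicate 18) and 2038 (without TCMR replicate 11). Quantile normalization gave 825 genes, 468 higher and 357 lower. Scaling to the FPKM outside mitochondrial, 7SL and 7SK rows, chosen after the data were seen, gave 0 genes with limma, with 2734 at an unadjusted p under 0.05. Log2 differences below are those of the deposited FPKM unless scaling is named. Median-of-ratios scaling gives changes relative to the typical gene. Of 30 lists, fry called 20 on the deposited FPKM, 20 higher and 0 lower, and 16 after scaling, 11 higher and 5 lower.

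All 19 tested members of the interferon gamma response list rose in TCMR, as did 19 when adjusted over the list alone, and 15 rose after scaling, 18 when adjusted over the list alone. The immunoproteasome subunits PSMB8 and PSMB9, which cut proteins into peptides for presentation, rose by 1.40 ± 0.28 and 1.65 ± 0.33 (SE), and by 0.97 and 1.23 after scaling. TAP1, which carries peptides into the endoplasmic reticulum, rose by 1.59 ± 0.34 (SE) and GBP5, a guanylate-binding protein induced by interferon, by 1.78 ± 0.44 (SE). The chemokines CXCL10 and CXCL9, which attract activated T cells, rose by 1.21 ± 0.29 and 0.84 ± 0.21 (SE). The list was called by camera with a preset correlation (adjusted p = 1.69e-07) and by fry after scaling (adjusted p = 0.000345), and its adjusted p = 0.434 with an estimated correlation.

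All 11 tested MHC class II genes and all 8 class I genes rose in TCMR, over all genes and adjusted over the list alone. After scaling, 9 and 7 of them passed, 11 and 8 when adjusted over the list alone. HLA-DQA1 rose by 1.68 ± 0.38, HLA-DPB1 by 1.73 ± 0.42, and HLA-DMA, which helps to load peptides, by 1.33 ± 0.32 (SE) and by 0.88 after scaling. The class I genes HLA-B, HLA-C and HLA-F rose by 1.90, 1.73 and 1.63, with 1.14 for HLA-C after scaling. Reads of these similar and highly variable genes can be split between them, so the share of each is uncertain. The adjusted p with an estimated correlation was 0.516 for either list, and the fry adjusted p after scaling was 0.00308 for class II and 0.000777 for class I.

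Lymphocyte genes rose from low levels. All 13 tested T cell genes rose, 13 when adjusted over the list alone, and after scaling 4 and 13 did. LCK, the kinase that starts signalling from the T cell receptor, rose by 1.10 ± 0.29 (SE), from a mean log2 level of 0.60 ± 0.57 (SD, n = 27) in NR to 1.71 ± 1.33 (SD, n = 22) in TCMR. The receptor constant gene TRBC2 rose by 1.45 ± 0.41 and the kinase ZAP70 by 0.94 ± 0.27 (SE). Of 12 cytotoxic effector genes 11 rose, 12 when adjusted over the list alone, and after scaling 3 and 10. They included the granule genes NKG7, higher by 1.24 ± 0.33, and GZMA, higher by 1.14 ± 0.34 (SE). Fry after scaling gave an adjusted p of 0.0166 for the T cell list and 0.00944 for the cytotoxic list, and the adjusted p with an estimated correlation was 0.581 for either. Of 3 tested NK cell genes 2 rose, 2 when adjusted over the list alone, KLRD1 among them by 0.88 ± 0.25 (SE). After scaling 1 rose, and 1 rose and 1 fell when adjusted over the list alone.

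Macrophage genes rose with them. Of 17 tested monocyte and macrophage genes 16 rose, 17 when adjusted over the list alone, and after scaling 5 and 13. LYZ (lysozyme) rose by 1.73 ± 0.46, C1QB, a chain of complement C1q made by macrophages, by 1.45 ± 0.39, FCGR1A, a high-affinity antibody receptor, by 1.03 ± 0.28, and the mannose receptor MRC1 by 0.90 ± 0.24 (SE), which was 0.57 after scaling. The fry adjusted p after scaling was 0.00672 and the adjusted p = 0.581 with an estimated correlation. The neutrophil list was not called by camera as deposited (adjusted p = 0.414), and was called higher after scaling (0.0251, and 0.617 with an estimated correlation). Of its 16 genes 11 rose, 12 when adjusted over the list alone, among them the formyl peptide receptor FPR1 by 1.46 ± 0.50 (SE), and 0 rose after scaling (FPR1 0.98, limma adjusted p = 0.13). S100A9, the most abundant of them, had a mean log2 level of 10.48 ± 1.53 (SD, n = 22) in TCMR and 10.47 ± 1.78 (SD, n = 27) in NR. A list of 11 genes known as the common rejection module, which earlier work derived from graft biopsies, rose in full (11 of 11, and 8 after scaling), with a fry adjusted p of 0.00016 after scaling and an adjusted p = 0.434 with an estimated correlation. The module shares CXCL9, CXCL10, PSMB9 and TAP1 with the interferon gamma list, LCK and CD6 with the T cell list and NKG7 with the cytotoxic list. Its result is therefore not separate from theirs. How far earlier work had drawn on these recipients was not examined here.

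**Figure D2:**
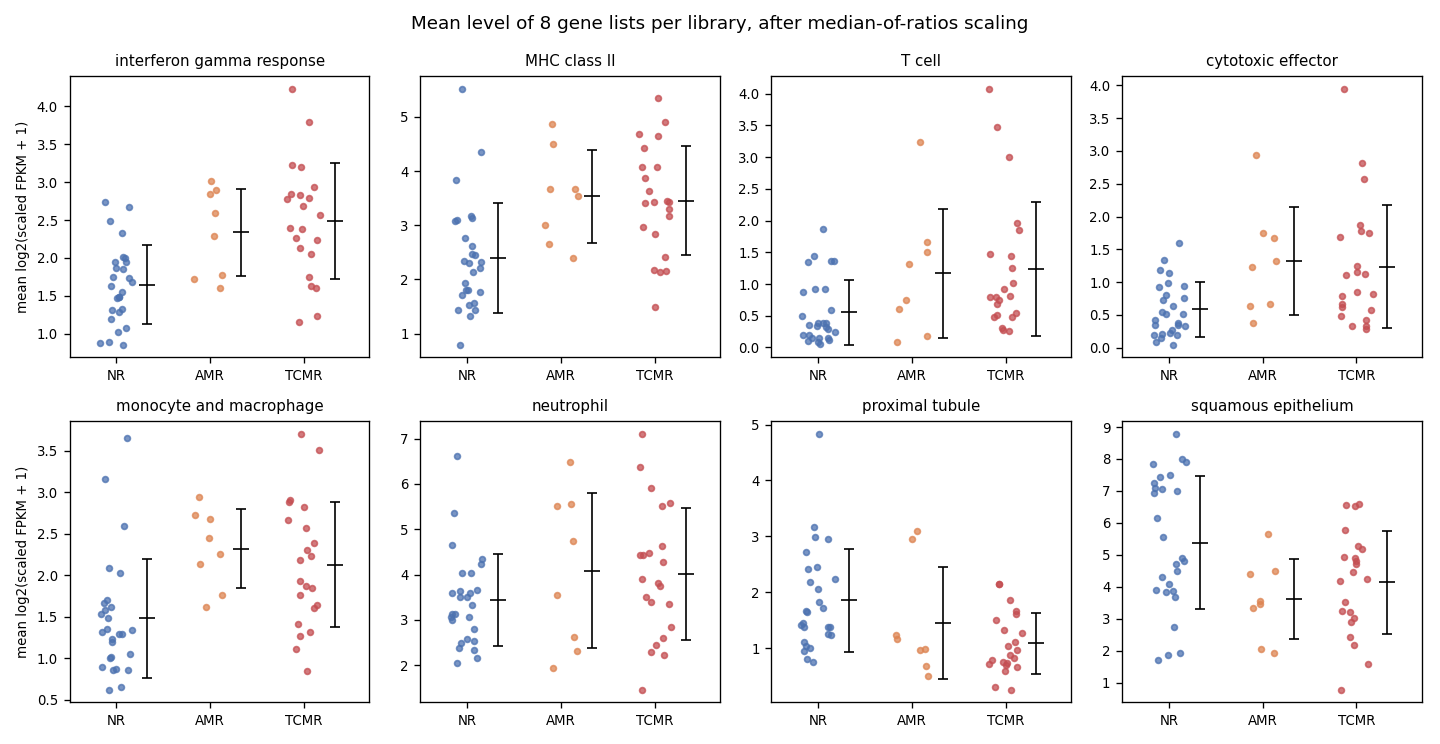
Mean log2(scaled FPKM + 1) over the tested members of 8 gene lists, after median-of-ratios scaling. Points are libraries of the NR, AMR and TCMR groups with the group mean and SD as black bars, the interferon gamma response averages 1.65 in NR, 2.34 in AMR and 2.49 in TCMR, the proximal tubule list averages 1.85, 1.45 and 1.08, and the groups overlap for every list.

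Tubular genes lay lower. Of 16 tested proximal tubule genes, 4 fell in TCMR, 4 when adjusted over the list alone. After scaling 4 fell, 13 when adjusted over the list alone. Beside GATM, they included MIOX (myo-inositol oxygenase, which fell by 1.24, SE 0.40) and GPX3 (the plasma glutathione peroxidase made by the kidney, which fell by 1.12, SE 0.35). The list was called by camera (adjusted p = 2.63e-17) and by fry after scaling (adjusted p = 0.0134). It was not called by fry as deposited (adjusted p = 0.126), and its adjusted p = 0.12 with an estimated correlation. The loop of Henle and distal tubule list, with 6 tested genes, and the collecting duct list, with 8, were called lower by camera (adjusted p = 1.55e-05 and 0.000231) and by fry after scaling (adjusted p = 0.0277 and 0.0224), but not by fry as deposited (adjusted p = 0.235 and 0.576). No gene of the loop list passed, over all genes or adjusted over the list alone, and after scaling 0 and 2 fell. KNG1 (kininogen) had a log2 difference of -0.31 (limma adjusted p = 0.0532). In the collecting duct list, ATP6V1B1, a proton pump subunit, fell by 0.34 (SE 0.14), and 0 fell when adjusted over the list alone, 1 after scaling. The adjusted p with an estimated correlation was 0.12 for each of these lists.

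Squamous epithelium, from the outer urinary tract, lay lower as well. All 20 tested squamous genes had a negative log2 difference, with a median of -0.77, and 2 passed over all genes, 0 when adjusted over the list alone. After scaling 2 fell, 12 when adjusted over the list alone. KRT1 (keratin 1) fell by 1.02 (SE 0.37) and TGM3 (a transglutaminase of the cornified envelope) by 1.05 (SE 0.43). Camera called the list lower (adjusted p = 1.25e-18), the fry adjusted p was 0.166 as deposited and 0.0301 after scaling, and the adjusted p = 0.12 with an estimated correlation. The TCMR libraries also held more detected genes than the NR libraries (8125 against 6474 on average), a difference that goes with each gene group above. With the number of detected genes as a covariate after scaling, a fit chosen after the data were seen, fry called 5 lists. They were the interferon gamma response (adjusted p = 0.0145), MHC class I (0.0221), common rejection module (0.00827), fatty acid oxidation (0.0221) and urine panel (0.0483) lists. Of their scaled median log2 difference, the first 3 kept 73.4%, 67.7% and 71.6%, and the others 85.2% and 64%. The common rejection module and urine panel lists share CXCL9 and CXCL10 with the interferon gamma list, so these calls are not separate. The T cell list kept 81.1% (fry adjusted p = 0.147), cytotoxic effectors 67.3% (0.108), macrophages 59.1% (0.108), class II 66.8% (0.0806) and squamous epithelium 81.6% (0.147). The proximal tubule median was -0.51 without and with this covariate (100% kept, fry adjusted p = 0.0779). The loop of Henle and distal tubule list kept 62.9% (0.288) and the collecting duct list 57.8% (0.277). With a score of 13 general leukocyte genes as covariate instead, fry called 0 lists (lowest adjusted p = 0.0503), and the share kept differed between lists. It was 79.8% for T cells, 79.1% for cytotoxic effectors, 72.3% for the proximal tubule, 66.5% for class II, 57.3% for squamous epithelium, 54.8% for the common rejection module, 45.2% for the interferon gamma response, 37.5% for macrophages and 29.8% for class I. The loop of Henle and distal tubule list kept 47% and the collecting duct list 23.8%. The neutrophil median turned from 0.86 to -0.46. Camera called 4 further lists lower in TCMR, in which no gene fell. These were urothelium (adjusted p = 0.0142, and adjusted p = 0.581 with an estimated correlation), red blood cell (0.00581 and 0.581), fatty acid oxidation (0.0142 and 0.581) and prostate and seminal tract (0.000439 and 0.434). Camera compares a list with all other genes, so its sign can differ from that of the list's median. The median log2 difference was 0.28 for urothelium, 0.08 for red blood cell and 0.07 for fatty acid oxidation, against the sign of the test. For prostate and seminal tract it was -0.18. After scaling the urothelium and fatty acid oxidation medians were negative (-0.10 and -0.35). Camera then still called fatty acid oxidation (adjusted p = 0.00198) but not urothelium (0.14), red blood cell (0.933) or prostate and seminal tract (0.0957).

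Other genes past the threshold with the largest differences were SRGN (the proteoglycan of immune granules, higher by 1.82 ± 0.57), CD52 (a lymphocyte and monocyte surface protein, 1.80 ± 0.39) and IFITM1 (an interferon-induced membrane protein, 1.79 ± 0.49; SE throughout). SRGN did not pass after scaling (limma adjusted p = 0.0754). The processed pseudogene TMSB4XP6 had the largest difference, 2.55 ± 0.62 (SE), but its reads can come from the thymosin gene it copies, so its source is uncertain. The histone genes HIST2H2AA3 and HIST2H2AA4, near-identical copies with uncertain shares, were both higher by 1.83 ± 0.41 (SE). Among lower genes were HPD, an enzyme of tyrosine breakdown that fell by 1.02 (SE 0.40), and ALDH3A1, an aldehyde dehydrogenase that fell by 0.92 (SE 0.34). PDZK1IP1, a tubular membrane protein, fell by 0.70 and PEBP1 by 0.67, and by 1.26 and 1.22 after scaling. MTRNR2L8 and MTRNR2L10 fell by 0.83 and 0.65, and by 1.39 and 0.98 after scaling, and as nuclear copies of mitochondrial ribosomal RNA they can hold mitochondrial reads.

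A panel of 15 genes from earlier polymerase chain reaction assays of urine had 12 tested members. CXCL9, CXCL10, CD3E, PRF1 and GZMB among them also belong to the interferon gamma, T cell and cytotoxic lists above. Of the 12 tested members, some therefore repeat results given there. Of the 12, 8 rose, 9 when adjusted over the list alone, and after scaling 4 rose over all genes, and 7 rose and 1 fell when adjusted over the list alone. CD3E, a chain of the T cell receptor complex, rose by 0.93 ± 0.28, the granule proteins PRF1 and GZMB by 0.72 ± 0.25 and 0.89 ± 0.25, and ITGAE, an integrin of T cells in epithelia, by 0.54 ± 0.17 (SE). SERPINB9, an inhibitor of granzyme B, rose by 1.02 ± 0.30 and VIM (vimentin) by 1.63 ± 0.41 (SE). After scaling GZMB, VIM, CXCL10 and CXCL9 passed, while CD3E (0.66, limma adjusted p = 0.0596), PRF1 (0.52, adjusted p = 0.0852), ITGAE (0.23, adjusted p = 0.219) and SERPINB9 (0.62, adjusted p = 0.0648) did not. GZMB was above the NR median in 19 of 22 TCMR libraries and CXCL10 in 17 of 22. TGFB1 (0.62, limma adjusted p = 0.05, just over the threshold), CXCR3 (0.30, adjusted p = 0.187), SLC12A1 (-0.28, adjusted p = 0.136) and UPK1A (-0.15, adjusted p = 0.76) did not pass. Camera did not call the panel (adjusted p = 0.231, and 0.712 with an estimated correlation). After scaling its adjusted p was 0.0145 by camera, 0.00206 by fry and 0.255 with an estimated correlation.

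**Figure D3:**
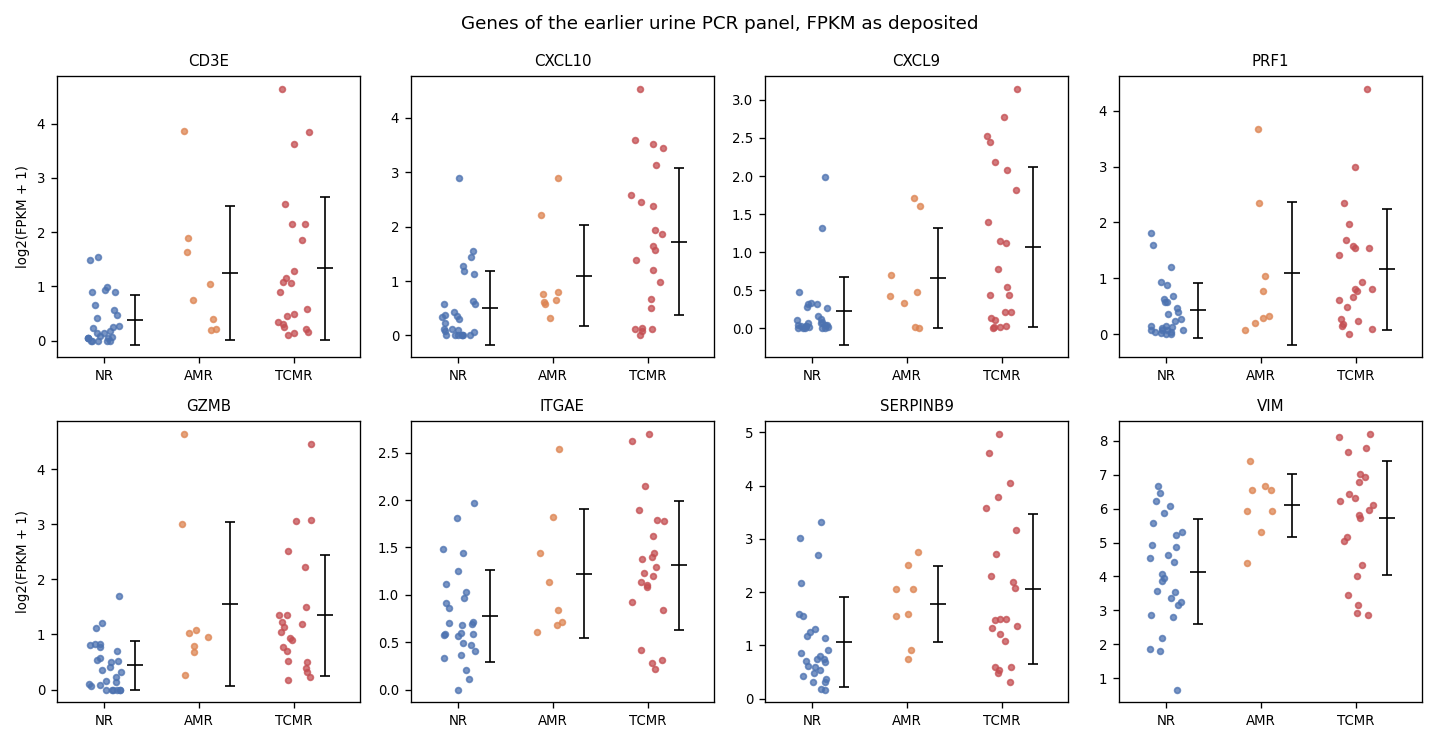
log2(FPKM + 1) of 8 genes of the earlier urine panel, with the FPKM as deposited. Points are libraries of the NR, AMR and TCMR groups with the group mean and SD as black bars, GZMB reaches at most 1.69 in NR, 4.64 in AMR and 4.46 in TCMR, and the groups overlap for every gene.

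Within each series of library names few genes passed. In a fit of the 18 TCMR and 23 NR libraries whose names start with GEM, 0 genes passed limma (lowest adjusted p = 0.0579, 4530 genes at an unadjusted p under 0.05), and the interferon gamma list had a median log2 difference of 1.02 with all 19 members positive (fry adjusted p = 0.012). In the 4 and 4 libraries whose names start with U, 2 genes passed, and that list's median was 2.51 with all 19 members positive (limma's fry, adjusted p = 0.0627). After scaling, 0 genes passed in the GEM libraries (2189 at an unadjusted p under 0.05) and 1 in U, and the list's median was 0.61 in GEM and 1.75 in U, with fry adjusted p of 0.0222 and 0.0642. Column headers divide the GEM series again by the letters RG. With RG (13 and 11 libraries) and without (5 and 12) 0 genes passed limma as deposited (4981 and 313 at an unadjusted p under 0.05), and after scaling all 19 members were positive in both, with medians of 0.59 and 0.83 (fry adjusted p = 0.114 and 0.0719).

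The second comparison set AMR against no rejection. Genes of macrophages and of antigen presentation were among those higher in AMR. C1QB (chromosome 1, 22652762 to 22661538) was higher by 2.30 ± 0.56 (SE, n = 8 and 27, limma adjusted p = 0.0295), and it lay above the NR median in 8 of 8 AMR libraries. HLA-DRA was higher by 2.41 ± 0.67 and CD74 by 2.29 ± 0.65 (SE), each in 8 of 8 libraries. FCER1G, the signalling chain of several antibody Fc receptors, was higher by 2.45 ± 0.64 (SE) in 7 of 8. With the FPKM as deposited 2975 genes passed limma, 2970 higher and 5 lower, and the median gene was 0.44 higher. After median-of-ratios scaling 0 genes passed limma (lowest adjusted p = 0.0706), 2534 had an unadjusted p under 0.05, and the exact rank-sum test called 0 genes on the deposited values.

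A score of 13 general leukocyte genes, after scaling, was higher as well. It averaged 3.85 ± 0.93 (SD, n = 8) in AMR, 3.83 ± 1.08 (SD, n = 22) in TCMR and 2.81 ± 0.97 (SD, n = 27) in NR. By list, 13 of 17 monocyte and macrophage genes rose, 16 when adjusted over the list alone. FCGR1A rose by 1.67 ± 0.39, the scavenger receptor CD163 by 1.69 ± 0.44 and C1QA by 1.92 ± 0.51 (SE). All 11 class II genes rose, HLA-DMB among them by 1.63 ± 0.44, and 7 of 8 class I genes, with B2M, the light chain of class I molecules, higher by 2.03 ± 0.58 (SE). Adjusted over the list alone, these were 11 and 8. Of 19 interferon gamma response genes 11 rose, 15 when adjusted over the list alone, including PSMB8 by 1.68 ± 0.40 (SE). Of 15 ribosomal protein genes 9 rose, 12 when adjusted over the list alone, with RPS12 higher by 1.47 ± 0.47 (SE). Camera called these 5 lists higher, with adjusted p of 0.000356, 0.00084, 0.00889, 0.00475 and 0.0193 in the order given here, and their adjusted p with an estimated correlation was 0.77, 0.77, 0.796, 0.909 and 0.97. Fry on the deposited FPKM called 9 lists, 9 higher, with an adjusted p of 0.0185, 0.0185, 0.0185, 0.0201 and 0.0254 for these 5. The others were dendritic cell (0.0201), common rejection module (0.0212), complement (0.0303) and tubular injury (0.0421). By fry after scaling no list passed (lowest adjusted p = 0.0648), while camera after scaling called 13 lists, 10 higher and 3 lower, and 0 of them held with an estimated correlation (lowest adjusted p = 0.471). The 10 were these 5 and the T cell (camera adjusted p after scaling 0.00876), cytotoxic effector (0.000617), common rejection module (0.00429), neutrophil (0.0124) and type I interferon (0.0377) lists. The 3 were the squamous (2.51e-09), proximal tubule (0.0411) and fatty acid oxidation (0.0406) lists. After scaling 0 of their members passed over all genes, and adjusted over the list alone 10, 10, 5, 6 and 0 rose. The scaled log2 difference was 1.499 for CD74, 1.19 for B2M, 1.06 for PSMB8 and 0.67 for RPS12.

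None of the 13 T cell genes passed in AMR, over all genes or adjusted over the list alone, although all 13 had a positive log2 difference with a median of 0.78. Of 12 cytotoxic effector genes 2 rose, 2 when adjusted over the list alone. Of the urine panel, GZMB rose by 1.01 ± 0.36 and VIM by 2.22 ± 0.59 (SE), with 1.47 for VIM after scaling. The log2 level of GZMB was 4.64 in AMR replicate 1 and 3.01 in AMR replicate 8. In the other AMR libraries it was at most 1.09, within the NR range of up to 1.69. CD3E had a log2 difference of 0.78 (limma adjusted p = 0.108), PRF1 of 0.62 (adjusted p = 0.152), CXCL10 of 0.56 (adjusted p = 0.256) and CXCL9 of 0.40 (adjusted p = 0.275). Squamous genes were lower on camera's test (adjusted p = 3.44e-24, and adjusted p = 0.193 with an estimated correlation), with 0 of 20 past the gene test as deposited, over all genes. After scaling 0 fell, 17 when adjusted over the list alone. CRNN (cornulin) had a log2 difference of -2.32 (limma adjusted p = 0.0714) and TGM3 of -1.49 (adjusted p = 0.0579). Camera also called lower the proximal tubule (adjusted p = 2.61e-05), loop of Henle and distal tubule (0.00447), collecting duct (0.0125), prostate and seminal tract (0.0125), urothelium (0.0193) and endothelium (0.0472) lists, in which no gene fell. In this order their adjusted p was 0.77, 0.619, 0.592, 0.77, 0.862 and 0.619 with an estimated correlation. The median log2 difference was positive, against the sign of the test, for collecting duct (0.19), prostate and seminal tract (0.07), urothelium (0.39) and endothelium (0.01). After scaling these medians were -0.20, -0.20, -0.15 and -0.36, and camera did not call these lists (adjusted p = 0.178, 0.4, 0.178 and 0.397) or the loop list (0.0918). Of 5 tested endothelium genes 1 rose, 1 when adjusted over the list alone, and 2 fell when adjusted over the list alone after scaling. It was PECAM1, an adhesion molecule of endothelium and leukocytes (1.30 ± 0.43, SE, limma adjusted p = 0.033, and 0.2 after scaling).

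Other genes with large positive differences in AMR were IL1R2, a decoy receptor for interleukin 1 (2.63 ± 0.82), SRGN (2.63 ± 0.81), IFITM1 (2.35 ± 0.70) and IFITM3 (2.29 ± 0.60), with SE after each. The pseudogenes TMSB4XP6 and TMSB4XP1 were higher by 3.36 and 2.82, with reads that can come from the thymosin gene. ALDH3A1 fell by 1.32 and TENT5B by 0.98. The count for AMR rested on single libraries and on the covariate. Leaving out AMR replicate 1, 4 or 6 gave 0 genes, leaving out AMR replicate 8 gave 16, and leaving out NR replicate 2 or 3 gave 1866 or 1267. Without a term for the series of library names 0 genes passed, and 0 with the 3 header series as the term. In GEM libraries 93 genes passed with all groups in the fit and 3031 with AMR and NR alone (5 and 23 libraries), in U libraries 1 and 6, and in the GEM libraries without RG (5 and 12) 0.

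In both comparisons against NR, 2621 genes passed in the same direction, 2617 higher and 4 lower. The NR libraries are shared, and 40 simulated sets of unchanged groups gave 0 shared genes at the median and at most 0. Those sets held no group effect, so their 0 cannot say how much shared controls add where both groups differ from NR. Independent lists of these sizes would share 1360 higher and 0.0225 lower genes. The NR libraries were also split at random into 13 for TCMR and 14 for AMR. In 20 splits the median was 0 shared genes and the highest 352. Each comparison then had fewer controls, and the calls per split are not given here. Overlap lost with unshared controls and overlap lost with fewer calls therefore cannot be told apart. After median-of-ratios scaling 0 genes passed in AMR against NR, so the shared count of 0 was fixed. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.849, against a mean of 0.352 in the simulated groups and a median of 0.734 with split controls. Their covariance was 0.152, against 0.0185 in the simulated groups, a difference of 0.133.

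The third comparison set TCMR directly against AMR. It is also the test of whether the differences from NR differ between the diagnoses. No gene passed limma as deposited or after scaling, with 123 and 204 genes at an unadjusted p under 0.05 where chance gives 579, and the exact rank-sum test called 0. CXCL10 had a log2 difference of 0.64 ± 0.42 (SE) and CXCL9 of 0.44 ± 0.31 (SE) with TCMR minus AMR, and VIM of -0.59 ± 0.60 (SE). The proximal tubule genes MIOX and PDZK1 had differences of -1.12 ± 0.59 and -0.85 ± 0.40 (SE), and the early response genes EGR1 and JUN of 0.60 ± 0.49 and 0.53 ± 0.43 (SE). Each of these had a limma adjusted p of 1. Camera called 11 of 30 lists, 8 higher and 3 lower in TCMR, with the squamous (adjusted p = 1.21e-05), stress (0.00048), T cell (0.000725), common rejection module (0.00383), urine panel (0.00684), lymphocyte chemokine (0.00945), interferon gamma (0.0146) and T cell checkpoint and regulatory (0.0227) lists higher and the proximal tubule (0.000106), nuclear oxidative phosphorylation (0.000473) and ribosomal protein (0.038) lists lower. After scaling camera called 5. The squamous (adjusted p = 0.00522) and stress (0.000139) lists were higher, and the proximal tubule (0.000139), nuclear oxidative phosphorylation (0.000139) and monocyte and macrophage (0.00528) lists lower. The T cell (0.152), common rejection module (0.0817), urine panel (0.169), lymphocyte chemokine (0.273), interferon gamma (0.0811), checkpoint (0.334) and ribosomal protein (0.163) lists were not called then. With an estimated correlation 0 lists were called (lowest adjusted p = 0.745), fry called 0, and no member of any list passed the gene test.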

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

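Tests of the few abundant rows, of the header series (except for AMR), of list calls with either covariate and of random splits for TCMR against AMR were chosen after the result was seen. Among 62 sets of values in the 8 AMR libraries (32 genes and 30 list means), 5 had 1 library farther from the rest than Dixon's 95% critical value allows. Chance alone gives about 1 in 20. TMSB4XP1 was listed at 0 in AMR replicate 2 while the next library stood at 4.15 on the log2 scale (gap over range 0.813). AMR replicate 8 was highest for CD3E, at 3.87 against 1.88 for the next library (0.54), and for the mean of the T cell checkpoint and regulatory list, at 1.89 against 1.09 (0.573). AMR replicate 6 was highest for the type I interferon list, at 4.16 against 2.44 (0.629), and AMR replicate 7 for the extracellular matrix list, at 2.59 against 1.64 (0.58).

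Nearly all genes called in TCMR against NR as deposited were higher in TCMR. A shift between header series is argued against as the source, because with the series as a covariate 98.2% of 5261 calls were still higher. The size of the difference was uneven within the series, which a covariate does not take up. The median gene was 0.44 higher in TCMR in GEM libraries with RG and 0.60 in U libraries. In GEM libraries without RG (5 and 12) it was 0.03 higher. A few abundant mitochondrial and 7SL rows are a candidate source of the shift. After scaling to the FPKM outside those rows the median gene kept 29.3% of its log2 difference, 0.10 of 0.35. Then 0 genes passed limma (2734 at an unadjusted p under 0.05). That scaling takes out any shift the other genes share, so it cannot tell this source from a higher content of nuclear gene RNA. Mitochondrial rows took on average 44.2% of the FPKM sum in TCMR and 54.2% in NR. The 7SL and 7SK rows took on average 17.6% and 17.5%, so only the mitochondrial share was lower in TCMR. MT-RNR2, listed at 0 in 6 libraries whose groups are not given here, can make their mitochondrial share too low. Median-of-ratios scaling, the test first written for this, centres the genes by construction and cannot decide it either. A higher content of nuclear gene RNA in TCMR pellets stays open and was not tested.

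The genes called in AMR against NR kept 94.9% of their median log2 difference with the header series as covariate (0.75 of 0.79), which argues against that series as the source of its size. The calls ended all the same, at a lowest adjusted p of 0.0543, with that smaller difference and a median SE of 0.269 in place of 0.261, and which of the changes ended them was not tested. Scaling to the FPKM outside the abundant rows kept 58.4% of the difference (0.46, median SE 0.236) and also ended the calls (lowest adjusted p 0.14). Whether those rows or a change in AMR pellets made the difference cannot be told apart. That share lies between the limits of 50% and 75% set for a decision, and the scaling takes out any shift the other genes share. Median-of-ratios scaling kept 40.2% but centres the genes by construction.

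Interferon gamma response genes after median-of-ratios scaling had a median log2 difference of 0.85 between TCMR and NR, and the header series is argued against, since the list kept 110% of it with that covariate (fry adjusted p = 6.41e-05). With the number of detected genes as covariate it kept 73.4% (fry adjusted p = 0.0145), just under the limit of 75%, so that cause cannot be told apart from the diagnosis. With a score of 13 general leukocyte genes, 0 of which another list holds, it kept 45.2% (fry adjusted p = 0.122), and all 19 members were positive with either covariate, while fry called 5 and 0 of the 30 lists with these covariates, against 16 without. LCP1 and PTPRC, among the most abundant genes of that score, were named after their values were seen. With the FPKM as deposited, LCP1 had a mean log2 level of 5.27 in TCMR and 3.58 in NR, and PTPRC of 5.12 and 3.42. The score, which was taken after scaling, was 3.83 ± 1.08 (SD, n = 22) and 2.81 ± 0.97 (SD, n = 27). A larger share of leukocytes in TCMR pellets may carry part of the difference, and share and response within cells cannot be told apart in bulk libraries whose score follows the diagnosis.

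Random splits of the same libraries bear on each count. For TCMR against NR, 1 of 100 splits, the real one, gave as many as 5358 genes, and the highest other gave 4276. After median-of-ratios scaling it was 1 of 100, with 1059 genes against 541 at most. For AMR against NR it was 1 of 100, with 2975 genes against 0. No other split drawn reached these counts, so they were rare among splits. With 100 splits a share under 1 in 100 cannot be seen. Labels were shuffled across the series of library names, over which the diagnoses are uneven, so chance is not excluded. The AMR count also became 0 without AMR replicate 1, 4 or 6. For TCMR against AMR all 100 splits gave at least the real count of 0, an outcome that a count of 0 fixes, so these splits say nothing about chance. Of the others 11 called genes, up to 5941, and a structure of the libraries other than the diagnosis is a candidate source that was not tested.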

How the results depend on the processing

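No paired analysis was possible because the labels give no shared replicate numbers. Settings with the header series, scaling outside the abundant rows, libraries of at least 4000 genes, the covariates for detected genes and leukocyte score, and combinations with median-of-ratios scaling were chosen after seeing the data. The cause was not tested for any change below unless stated. For TCMR against NR, the count of 5358 became 3382 with the stricter filter, where fewer genes were tested. It was 825 with quantile normalization and 1059 with median-of-ratios scaling. The count was 0 in GEM libraries (18 TCMR and 23 NR) and 1 in U libraries (4 and 4). The median log2 difference was 0.299 in GEM and 0.598 in U libraries, so smaller numbers and uneven effects cannot be told apart. Scaling outside mitochondrial, 7SL and 7SK rows gave 0. Median-of-ratios scaling gave 2288 with the header series, 0 in GEM libraries and 110 in libraries of at least 4000 genes. For AMR against NR, 2975 became 36 with no filter, 2 with quantile normalization, 0 with median-of-ratios scaling, no covariate, the term for b, the exact rank-sum test, the header series, scaling outside the abundant rows, libraries of at least 4000 genes, and each combination with median-of-ratios scaling. It was 93 in GEM, 1 in U, 5604 with 2 groups in the fit and 4660 with array weights. TCMR against AMR gave 0 in every setting run. Genes shared by both comparisons against NR, 2621 as reported, became 9 with no filter, 1 with quantile normalization, 0 with median-of-ratios scaling, no covariate or the term for b, 4453 with 2 groups in the fit and 4308 with array weights. Leaving out 1 library at a time gave 4043 to 6435 genes for TCMR against NR, 0 to 4168 for AMR against NR (1866 and 1267 without NR replicates 2 and 3, 0 without AMR replicate 1, 4 or 6, and 16 without AMR replicate 8) and 0 to 0 for TCMR against AMR. After median-of-ratios scaling the range for TCMR against NR was 231 to 2038, and 22 libraries moved it by over 1.5 times. It was 231, 380, 410, 423, 482, 498, 507, 508, 545 and 704 without TCMR replicates 18, 13, 2, 14, 1, 12, 10, 16, 9 and 4, and 338, 393, 516, 584, 603 and 624 without NR replicates 3, 23, 1, 24, 16 and 18. It was 1649, 1822 and 2038 without TCMR replicates 3, 8 and 11, and 1599, 1694 and 1732 without NR replicates 21, 7 and 5. For AMR against NR after that scaling the range was 0 to 5, with 3, 3, 4, 1, 5, 1 and 2 genes without TCMR 8, TCMR 16, NR 5, NR 11, NR 21, AMR 5 and AMR 8. Lists called, 15, 12 and 11 as reported for the comparisons in the order above, were 0, 0 and 0 with an estimated correlation and 19, 13 and 5 by camera after scaling. For TCMR against NR, fry after scaling gave 5 with detected genes and 0 with the leukocyte score as covariate. For AMR against NR, fry after scaling gave 0, with or without the header series, detected genes or the leukocyte score. For TCMR against AMR, fry gave 0, also after scaling and with each of these covariates, quantile normalization 6, no covariate 4 and GEM libraries 3. Among 73 genes named for TCMR against NR, 15 lost their call and 1 reversed after median-of-ratios scaling, and of 28 for AMR against NR, 22 lost it. Reversed log2 differences were those of S100A9 in TCMR against NR, -0.16 with quantile normalization, -0.55 with median-of-ratios scaling, -0.61 with the header series added, -0.20 in GEM libraries and, in the exact rank-sum test, 49% of library pairs with TCMR higher. Also reversed were CXCR3 (-0.006 with median-of-ratios scaling and header series), UPK1A (0.087 in GEM libraries) and ATP6V1B1 (0.017 in U libraries) in TCMR against NR, and VIM (0.017 in U libraries) in TCMR against AMR. The other named genes kept their direction in the settings run for them. List medians that turned from positive to negative after median-of-ratios scaling were, for TCMR against NR, those of urothelium (-0.10), fatty acid oxidation (-0.35), complement (-0.013), endothelium (-0.21), extracellular matrix (-0.032) and nuclear oxidative phosphorylation (-0.11). For AMR against NR they were those of urothelium (-0.15), collecting duct (-0.20), prostate and seminal tract (-0.20), endothelium (-0.36), fatty acid oxidation (-0.26), stress (-0.29) and mitochondrially encoded genes (-0.58). For TCMR against AMR, medians turned from negative to positive for type I interferon (0.062), class I (0.11), plasma cell (0.002), inflammasome (0.043), urothelium (0.018) and extracellular matrix (0.028) genes. Depth is unknown, so its limit on low genes cannot be given.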

Other observations

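The list tests after scaling and the tests between series in this part were chosen after the data were seen. Genes of several other immune lists rose in TCMR against NR, while camera called none of the lists of this paragraph as deposited. Of all 11576 tested genes 5306 rose as deposited, so a count near that share does not set a list apart. After scaling camera called the lymphocyte chemokine (adjusted p = 0.0108), type I interferon (0.00198), inflammasome (0.016) and dendritic cell (0.0421) lists and not the checkpoint list (0.0733). None held with an estimated correlation (adjusted p = 0.255, 0.512, 0.476 and 0.255 after scaling). Of 8 tested lymphocyte chemokine genes 7 rose, CCL5 among them by 1.62 ± 0.39 (SE), and 1 rose after scaling, 1 when adjusted over the list alone. The fry adjusted p after median-of-ratios scaling was 0.0035 (adjusted p = 0.581 with an estimated correlation as deposited). Of 5 T cell checkpoint and regulatory genes 4 rose (fry adjusted p after scaling 0.0224, and adjusted p = 0.675 with an estimated correlation). HAVCR2, which encodes the receptor TIM-3, was higher by 0.99 ± 0.24 and PDCD1, which encodes PD-1, by 0.66 ± 0.19 (SE), and both passed after scaling (limma adjusted p = 0.0212 and 0.0409). Of 18 type I interferon genes 13 rose, OASL among them by 1.06 ± 0.24 (SE), and 1 rose after scaling (fry adjusted p = 0.0938). The camera adjusted p of that list as deposited was 0.0849, and 0.807 with an estimated correlation. Of 15 inflammasome and interleukin 1 family genes 8 rose, with PYCARD, the adaptor of inflammasomes, higher by 1.07 ± 0.25 (SE) and by 0.67 after scaling, and 1 rose after scaling (fry adjusted p = 0.0652, camera adjusted p as deposited 0.278, and 0.854 with an estimated correlation). Of 5 dendritic cell genes 4 rose, and 1 after scaling (fry adjusted p = 0.00451). That 1 was GZMB, which the cytotoxic effector and urine panel lists also hold. The dendritic cell list had an adjusted p = 0.625 with an estimated correlation, and 0.255 after scaling. Of 3 B cell genes 2 rose, CD72 by 0.63 ± 0.13 and MS4A1 by 0.66 ± 0.27 (SE). After scaling 1 rose, CD72 by 0.40, and MS4A1 did not pass (limma adjusted p = 0.117). None of 4 plasma cell genes passed, and IGKC had a log2 difference of 0.85 (limma adjusted p = 0.065).

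Tissue and quality lists in TCMR against NR gave smaller or less even values. Their counts as deposited are also to be read against the 5306 of 11576 genes that rose. Fatty acid oxidation genes lay lower after scaling, where 4 of 13 fell and the fry adjusted p was 0.00308 (adjusted p = 0.255 with an estimated correlation), while 2 rose with the FPKM as deposited, so the direction depends on the scaling. Of 15 tubular injury genes 6 rose as deposited, with CD44 higher by 1.37 ± 0.41 and SPP1 (osteopontin) by 1.11 ± 0.39 (SE), and after scaling 1 rose and 1 fell (fry adjusted p = 0.807), while CD44 (0.84) and SPP1 (0.56) did not pass (limma adjusted p = 0.0742 and 0.212). Of 15 stress genes 8 rose as deposited, FOS by 1.37 ± 0.46 and JUN by 0.95 ± 0.30 (SE), and 0 after scaling. Of 15 ribosomal protein genes 12 rose as deposited, RPS12 by 1.12 ± 0.33 (SE), and 0 after scaling. Of 11 proliferation genes 3 rose, MCM2 by 0.45 ± 0.15 (SE), and 0 after scaling. The complement list had 4 of 13 genes higher, the endothelium list 2 of 5 (PECAM1 by 0.94 ± 0.30, SE, and 0.51 after scaling), the podocyte list 1 of 3 and the extracellular matrix list 1 of 5, and after scaling 0 of each rose and 1 complement gene fell. Adjusted over the list alone as deposited, 7 lymphocyte chemokine, 4 checkpoint, 16 type I interferon, 9 inflammasome, 4 dendritic cell, 2 B cell, 1 fatty acid oxidation, 6 tubular injury, 9 stress, 12 ribosomal protein, 2 proliferation, 2 complement, 2 endothelium, 1 podocyte and 1 extracellular matrix genes rose. After scaling 1 lymphocyte chemokine, 2 checkpoint, 1 type I interferon, 5 inflammasome, 3 dendritic cell, 2 B cell, 1 tubular injury, 2 endothelium and 1 extracellular matrix genes rose on that measure, and 7 fatty acid oxidation, 1 tubular injury, 1 complement, 2 endothelium and 2 nuclear oxidative phosphorylation genes fell. In the nuclear oxidative phosphorylation list 1 of 17 rose as deposited and 2 fell after scaling. No gene of the urothelium (16 tested), red blood cell (9), prostate and seminal tract (6) or mitochondrially encoded (9) lists passed over all genes with either scaling, and adjusted over the list alone 9 mitochondrially encoded genes fell after scaling. HBB, a globin, had a log2 difference of 1.10 ± 1.29 (SE), and MT-ND1 of -0.65 ± 0.35 (SE).

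In AMR against NR the remaining lists tested were not called by camera as deposited. Of all 11576 tested genes 2970 rose in AMR as deposited, so a count near that share does not set a list apart. Over all genes and adjusted over the list alone, 4 and 7 of 11 genes of the common rejection module rose, 3 and 3 of 18 type I interferon genes, 3 and 9 of 16 neutrophil genes and 4 and 11 of 17 nuclear oxidative phosphorylation genes. Over all genes, 2 of 5 dendritic cell, 5 of 15 inflammasome, 1 of 8 lymphocyte chemokine, 3 of 13 complement, 4 of 15 tubular injury, 3 of 11 proliferation, 1 of 5 checkpoint, 1 of 3 B cell and 1 of 5 extracellular matrix genes rose, with the same counts adjusted over the list alone. For fatty acid oxidation and stress it was 1 gene each and 0 adjusted over the list alone. No NK cell, plasma cell, podocyte, red blood cell or mitochondrially encoded gene passed. After scaling 0 genes of these lists passed over all genes, and adjusted over the list alone 2 common rejection module, 2 dendritic cell, 1 inflammasome, 1 tubular injury, 1 proliferation, 1 checkpoint and 1 B cell genes rose.

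Between the U and GEM libraries themselves 13 genes passed as deposited, and the TCMR difference from NR differed between these series for 0 genes as deposited and 1 after scaling (limma interaction, 316 and 876 genes at an unadjusted p under 0.05).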
